A study of Mus musculus with 20 samples.

How the data were processed

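Pancreas RNA of inceptor knockout and wild-type C57BL/6J mice was profiled at E18.5 (5 knockout and 4 wild-type arrays) and P0 (6 and 5). According to the labels, RNA was isolated with the RNeasy Lipid Tissue Kit, amplified with the NuGEN Ovation PicoSL WTA V2 kit, labelled with the Encore Biotin kit and hybridised to an Affymetrix mouse transcript array. Mothers were starved for 2 h before collection at E18.5 and pups for 5 h at P0, and the labels give neither sex nor litter. The deposited values are log2 signals that the authors background-corrected, normalised between arrays and summarised per transcript cluster by RMA in Affymetrix Expression Console 1.4.1.46. They run from 2.17 to a ceiling of 19.932, the log2 of 1000000, which 261 to 278 probe sets share on each array. The authors' notes do not state what produced this ceiling, so differences of genes at it are hidden. The lowest Pearson correlation between any 2 arrays over all probe sets was 0.979.

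Of 65956 probe sets, 30604 carried a single gene symbol, 2146 several and 33206 none in the deposited probe table. Symbols were updated to the mouse annotation of assembly GRCm38.p6, which also gave the order of genes along chromosomes. The array's own genome build was not named, so no coordinates are given. For a gene with several named probe sets, the one with the highest mean was used. Genes above the array median on at least 4 arrays were tested, which left 17993 of 30063, and 295 of these duplicate the values of another gene. A linear model with a mean for each of the 4 groups was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (16 residual and 17.9 total degrees of freedom after moderation). The contrasts, all two-sided, were knockout minus wild type at E18.5, at P0 and averaged over both ages, the difference of that effect between the ages, and P0 minus E18.5 within each genotype.

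P-values were adjusted over all tested genes by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p under 0.05 were called. Values are log2 differences ± SE unless given as SD. The labels do not say whether each array is a separate animal, so the p-values measure the spread between these samples. Replicate numbers were not treated as pairs. On simulated changes the fit recovered 47.0% of changes of 0.5 on the log2 scale, 77.0% of changes of 1 and 98.3% of changes of 2 at E18.5, and 45.6%, 90.4% and 100% at P0. The simulation changed many genes at once (66, 74 and 60 at these sizes at E18.5) and gave each gene independent noise. The real genotype contrasts called few genes and hold structure shared between arrays, so recovery in them can be lower.

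Before the data were examined, 43 gene lists were fixed from general knowledge of pancreatic cell types, metabolism, stress responses and neighbouring organs, of which 41 had at least 3 tested members. Lists were tested against all other genes by camera with a preset correlation of 0.01, adjusted over the lists within each contrast. The same lists were tested by camera with an estimated correlation and by fry, in one direction and in either. Members were also adjusted over the list alone. Members that differed from 0 by rounding only were counted neither above nor below 0. The lists share some genes, such as Pdk4. Array counts given for a list compare the mean of its tested members on an array with the mean of the other group.

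The rule for named genes was fixed with the lists. It took the inceptor gene; a fixed set of hormone, islet transcription factor, insulin signalling and cell cycle genes (Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Nkx6-1, Mafa, Insr, Igf1r, Irs1, Irs2, Mki67, Ccnd1, Ccnd2); in each contrast the 10 called genes with the largest rise and the 10 with the largest fall, or where fewer than 5 were called in a direction the 5 with the smallest unadjusted p, given as not passing; and for each list described up to 4 called members with the largest change, or if none was called up to 4 with the smallest unadjusted p. Predicted genes, microRNAs and small RNAs were counted but not named. Insr and Ins1 had no named probe set, Ccnd1 shared its probe set with another symbol and Mafa did not pass the signal filter, so these were not analysed here.

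The settings fixed with them were no signal filter and a stricter one, quantile normalisation again, centring on array medians, cyclic loess, eBayes with trend and robust settings, array weights, the arrays compared alone, a replicate block, the running sample number or the Y-linked level as a covariate, looser thresholds, the mean over a gene's probe sets and leaving out each array. Chosen after seeing the data were counting duplicate genes once, the liver and intestinal marker means as covariates, leaving out the 5 arrays with an intestinal or muscle marker mean over 7, smaller sets of knockout arrays, and centring and cyclic loess for the lists. Figures were drawn with matplotlib 3.10.9, and tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Arrays were named by group and replicate number. No array was left out of the results as reported.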

Results

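RNA from mouse pancreas was measured on 20 Affymetrix transcript arrays, in animals lacking inceptor and in wild-type controls at 2 ages around birth. Embryonic day 18.5 (E18.5) was represented by 5 knockout and 4 wild-type arrays, and the day of birth (P0) by 6 knockout and 5 wild-type arrays. Inceptor, the product of Elapor1 (named Iir in the labels), is a transmembrane receptor that dampens insulin receptor signalling. Array medians lay between 4.81 and 4.94 on the log2 scale, and the number of arrays sets the precision of every value. Age separated the arrays along the first principal component, which held 34.4% of the variance: scores ran from -41.9 to -17.6 at E18.5 and from 9.82 to 36.5 at P0. The second component held 9.89%. Marker genes of neighbouring organs also varied from array to array. The mean log2 signal of the liver markers ran from 6.30 to 12.1, that of the intestinal epithelium markers from 5.69 to 8.43, and that of the skeletal muscle markers from 4.84 to 7.47. Y-linked genes had a mean of 7.42 to 7.99 on 5 arrays (1 E18.5 knockout, 2 E18.5 wild type, 1 P0 knockout, 1 P0 wild type) and of at most 4.44 on the other arrays; the labels state no sex.

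**Figure D1:**
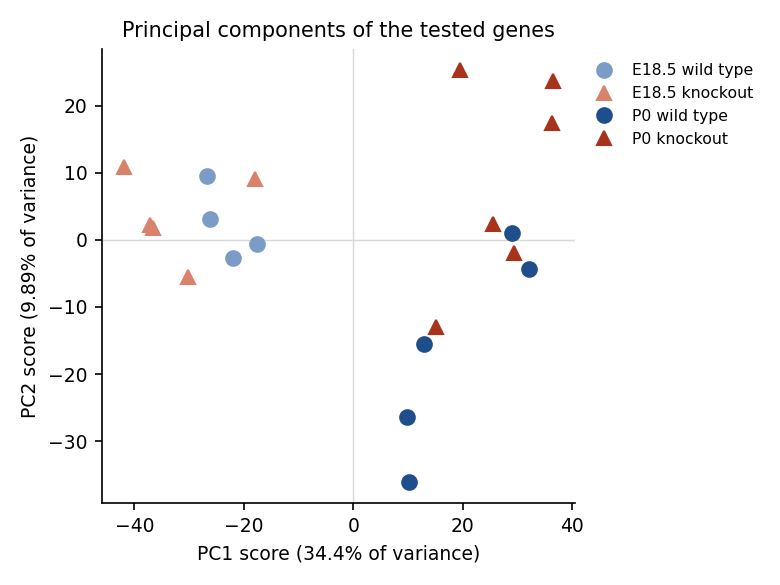
Scores of the 20 arrays on the first 2 principal components of the log2 values of the tested genes, which hold 34.4% and 9.89% of the variance. Each point is an array, by genotype and age: E18.5 arrays lie between -41.9 and -17.6 on the first component and P0 arrays between 9.82 and 36.5.

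The inceptor gene itself was lower in every knockout array at both ages. At E18.5 its log2 signal was 6.31 ± 0.30 (SD, n = 5) in knockouts and 11.86 ± 0.22 (SD, n = 4) in wild type, a level 46.8-fold lower (log2 difference -5.55 ± 0.19 SE, adjusted p = 4.13e-12). At P0 the signal was 6.05 ± 0.30 (SD, n = 6) in knockouts and 11.54 ± 0.35 (SD, n = 5) in wild type, 45.1-fold lower (-5.49 ± 0.18, adjusted p = 8.10e-13). Knockout arrays spanned 5.58 to 6.5 and wild-type arrays 11.1 to 12.1, without overlap. Between the ages Elapor1 did not pass the test in wild type (-0.32 ± 0.19, adjusted p = 0.333, lower in 4 of 5 P0 arrays) or in knockouts (-0.27 ± 0.18, adjusted p = 0.304, lower in 4 of 6). A single probe set carries the gene, under the older symbol 5330417C22Rik, so the signal left in knockouts cannot be split between background and remaining transcript.

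**Figure D2:**
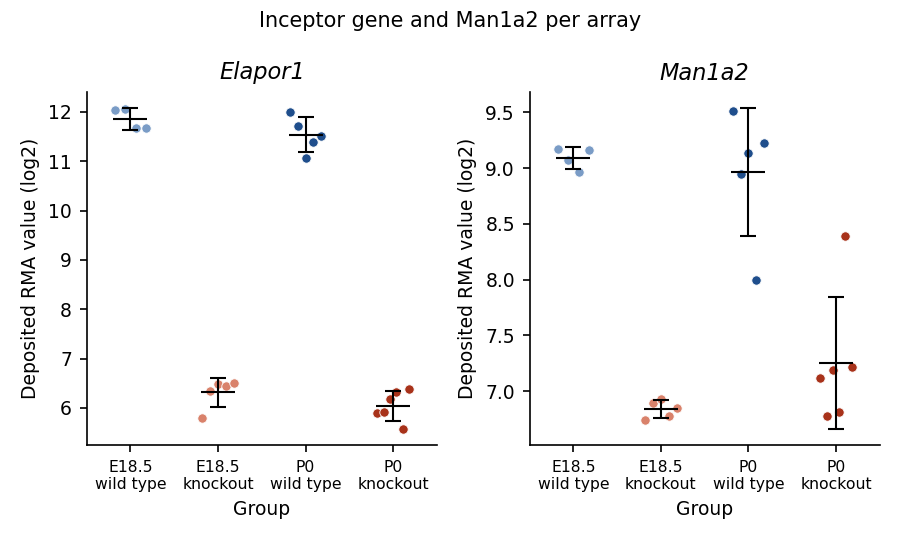
Log2 signal of Elapor1 and Man1a2 by genotype and age, with each dot an array, lines the group means and bars the SD. All knockout arrays lie below all wild-type arrays for Elapor1 (knockouts 5.58 to 6.5, wild type 11.1 to 12.1).

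At E18.5, the comparison of knockouts with wild type asked what inceptor loss changed before birth. Besides Elapor1, a single gene passed the test. Man1a2, a Golgi mannosidase that trims N-linked glycans, fell by 2.25 ± 0.28 on the log2 scale (adjusted p = 0.00236) and was lower in 5 of 5 knockouts than in every wild-type array. Mitochondrial respiratory chain genes ran higher as a group, with 35 of 38 above 0 at a median log2 difference of 0.16, among them Uqcrc2 (0.38 ± 0.12) of complex III and Ndufb3 (0.32 ± 0.12) of complex I. Mesenchymal and matrix genes ran lower, 21 of 22 below 0 at a median of -0.22, including fibronectin Fn1 (-0.74 ± 0.21) and decorin Dcn (-0.36 ± 0.16). Mitotic genes of the G2 and M phases were above 0 in 30 of 31 cases, with a median of 0.19 and Ube2c, which primes cyclins for degradation, at 0.40 ± 0.16. No member of these 3 groups passed the test by itself, with 0 called adjusted over the list alone in each.

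The gene count at E18.5 was 2 of 17993 tested, both lower. With limma 0 genes were called higher, while 980 genes had an unadjusted p under 0.05, where independent genes would give 899.7 by chance. With genotype labels shuffled among the E18.5 arrays the median was 617. Of 100 splits, the true one included, 6 gave as many. The count became 1 without the 5 arrays rich in intestinal or muscle markers (Man1a2 then -2.22, adjusted p = 0.192, a similar size from fewer arrays), 5 with array weights, and 4 without E18.5 knockout 2 or without P0 wild type 1. Among genes that did not pass, the smallest p-values belonged to Gpx2, a glutathione peroxidase of epithelia (0.52 ± 0.08, adjusted p = 0.0508, higher in 5 of 5 knockouts), Rida (0.71 ± 0.13, adjusted p = 0.145), the complex I assembly factor Ndufaf3 (0.53 ± 0.12), the tight junction gene Cldn10 (0.48 ± 0.10) and Wfdc15b (1.04 ± 0.23) on the higher side. On the lower side they belonged to Tnxb (-0.46 ± 0.10), Elfn1 (-0.31 ± 0.07), Tas2r121 (-0.47 ± 0.12), Olfr965 (-0.49 ± 0.13) and Amotl2 (-0.14 ± 0.04). The adjusted p of these 5 ranged from 0.491 to 0.592. Apart from Tnxb, their signals in knockouts lay near or below the array medians, so the sizes of these differences are uncertain.

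By the camera test, 11 of 41 lists passed at E18.5, 9 without the marker-rich arrays, and 5 without E18.5 wild type 4. With an estimated correlation 1 list passed, that of inceptor and its binding partners (adjusted p = 0.0017), which holds Elapor1. Respiratory chain genes had an adjusted p = 5.40e-08, with the list mean higher in 5 of 5 knockouts, and adjusted p = 0.593 with an estimated correlation. For mesenchymal genes the values were adjusted p = 2.79e-09, lower in 5 of 5 knockouts, and adjusted p = 0.266 with an estimated correlation. Mitotic genes had an adjusted p = 5.31e-05, higher in 4 of 5 knockouts, against adjusted p = 0.669 with an estimated correlation, and lost the call without E18.5 wild type 1 (adjusted p = 0.0717). Alongside these groups, liver markers were above 0 in 3 of 14 cases (median -0.75, adjusted p = 0.0959) and intestinal epithelium markers in 10 of 11 (median 0.30, adjusted p = 0.219). Skeletal muscle markers were so in 7 of 7 (median 0.22, adjusted p = 0.503).

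The lists of beta-cell genes and of insulin signalling did not pass at E18.5. The beta-cell list had 16 of 21 members above 0 at a median of 0.14 (camera adjusted p = 0.0959, higher in 5 of 5 knockouts), with the zinc transporter Slc30a8 at 0.53 ± 0.30 and the potassium channel subunit Kcnj11 at 0.36 ± 0.15. Glucagon (Gcg) stood at 0.48 ± 0.15, adjusted p = 0.747, higher in 5 of 5 knockouts. Pdx1, Nkx6-1, Sst, Ppy, Irs1, Irs2, Igf1r, Mki67 and Ccnd2 lay between -0.20 and 0.21, none with an adjusted p under 0.982, and Pdx1 had a signal near the array medians. The insulin and IGF signalling list had 13 of 33 members above 0 (median -0.020, adjusted p = 0.203). Of the non-beta islet hormones and regulators, which include Gcg, 7 of 9 were above 0 (median 0.15, higher in 4 of 5 knockouts, 1 member called higher adjusted over the list alone). This list was called by camera (adjusted p = 0.0314) but not with an estimated correlation (adjusted p = 0.669) or without the marker-rich arrays (0.221). The call was also lost without any of E18.5 knockouts 1, 3 and 5 and E18.5 wild types 1, 3 and 4 (adjusted p from 0.0712 to 0.16). Ins2 sat on a plateau of 18.58 on 19 of the 20 arrays, which hides any difference in its level, and Ins1 and the insulin receptor gene Insr, which have no named probe set, were not analysed here.

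At P0 the same comparison addressed inceptor loss on the day of birth, and Elapor1 and Man1a2 were again the genes past the test. Man1a2 fell by 1.71 ± 0.25 on the log2 scale (3.27-fold, adjusted p = 0.0251) and was below the wild-type mean in 6 of 6 knockouts, although P0 knockout 5 (8.39) lay above P0 wild type 4 (8.0). The P0 call of Man1a2 ended in 6 other settings, at adjusted p = 0.0623 to 0.536. Genes of fatty acid oxidation and ketogenesis ran lower, 18 of 19 below 0 at a median of -0.37, among them the long-chain dehydrogenase Acadl (-0.70 ± 0.23) and the trifunctional enzyme subunit Hadha (-0.63 ± 0.16). Transcription factors and secretory machinery of acinar cells were below 0 in 12 of 16 cases, at a median of -0.25, with Rbpjl at -1.17 ± 0.29 and Nr5a2 at -0.48 ± 0.14. Target genes that FOXO factors activate when insulin signalling is low ran higher, 13 of 16 above 0 at a median of 0.35, such as Sesn1 (1.86 ± 0.77) and Bnip3 (0.86 ± 0.39). Their mean signal did not follow genotype alone. It was 8.72 to 9.39 in P0 knockouts 2, 3, 4 and 6 and 8.77 to 8.87 in P0 wild types 3 and 5, against 8.19 to 8.36 in P0 knockouts 1 and 5 and 7.93 to 8.01 in P0 wild types 1, 2 and 4.

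The 2 cell cycle lists differed in direction at P0. Of the DNA replication genes of S phase, 24 of 25 were below 0 (median -0.15), among them the helicase subunits Mcm3 (-0.56 ± 0.21) and Mcm6 (-0.44 ± 0.17). Of the mitotic genes, 30 of 31 were above 0 (median 0.22), with Ube2c at 0.57 ± 0.15 and the spindle motor Kif11 at 0.42 ± 0.16. Respiratory chain genes were below 0 in 31 of 38 cases (median -0.10), including the succinate dehydrogenase subunit Sdha (-0.19 ± 0.08). Immediate early and heat shock genes were above 0 in 14 of 17 cases (median 0.19), such as Btg2 (1.17 ± 0.46) and Zfp36 (1.04 ± 0.36). Digestive enzymes of acinar cells had a median of 0.00, since 18 of 29 showed no difference. Of the others 10 were below 0 and 1 above, the mean was -0.26 and the test pointed down. In this list 18 members reached the ceiling of the scale on some array. The members furthest below 0 were Reg2 (-2.99 ± 0.59), a secreted lectin of acinar cells, and the phospholipase Pla2g1b (-1.79 ± 0.32).

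Camera called 15 of 41 lists at P0, 18 without the marker-rich arrays, and none of them kept the call with an estimated correlation. Beta oxidation had camera adjusted p = 8.55e-08, with the list mean lower in 6 of 6 knockouts, and adjusted p = 0.118 with an estimated correlation. Acinar transcription factors had adjusted p = 0.000189 (lower in 6 of 6) and adjusted p = 0.568 with an estimated correlation. Digestive enzymes had adjusted p = 0.00751 (lower in 6 of 6) and adjusted p = 0.118 with an estimated correlation. FOXO targets had adjusted p = 0.000213 (higher in 5 of 6) and adjusted p = 0.33 with an estimated correlation. S phase genes had adjusted p = 3.51e-05 (lower in 5 of 6) and mitotic genes 4.07e-08 (higher in 6 of 6). Both had adjusted p = 0.595 with an estimated correlation. Respiratory chain genes had adjusted p = 0.000742 (lower in 5 of 6) and adjusted p = 0.642 with an estimated correlation. P0 wild types 3 and 5 lay near the knockouts on some of these lists. For acinar transcription factors their means were 10.39 and 10.59, against 10.27 to 10.71 in P0 knockouts. P0 wild types 1, 2 and 4 had 11.09 to 11.16. In the same order, the values for S phase genes were 6.92 and 6.64, 6.77 to 7.11 and 7.19 to 7.39. Those for respiratory chain genes were 11.13 and 11.12, 11.05 to 11.32 and 11.37 to 11.44. These 3 differences did not follow genotype alone. Immediate early genes had adjusted p = 0.00214 (higher in 6 of 6) and adjusted p = 0.33 with an estimated correlation. By fry, which asks whether the genes of a list move on balance one way, beta oxidation and digestive enzymes had adjusted p = 0.0278. With the marker means as covariates the camera adjusted p of immediate early genes was 0.0893. No member of these 8 lists was called over all genes. Adjusted over the list alone, 5 members of beta oxidation, 4 acinar transcription factors and 3 digestive enzymes were called lower, and 1 mitotic gene higher. Liver markers were above 0 in 14 of 14 cases at P0 (median 1.63, adjusted p = 0.000112, and adjusted p = 0.595 with an estimated correlation), and lost their call without P0 wild type 5 (adjusted p = 0.054). Skeletal muscle markers were above 0 in 7 of 7 (median 0.34, adjusted p = 0.292) and intestinal markers in 5 of 11 (median -0.018, adjusted p = 0.353).

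**Figure D3:**
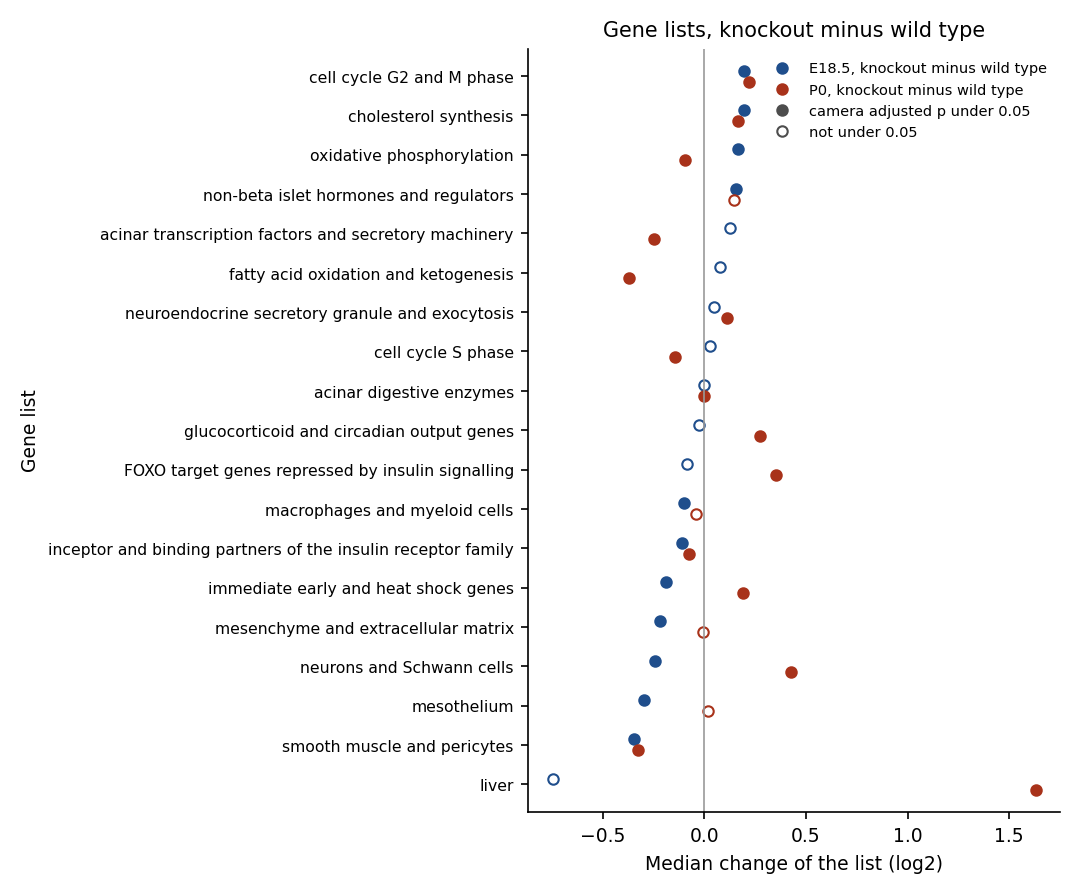
Median log2 difference (knockout minus wild type) at E18.5 and P0 of the gene lists with a camera adjusted p under 0.05 at either age, which filled markers show. Respiratory chain genes lie at 0.16 at E18.5 and at -0.10 at P0.

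Of 17993 genes, 2 were called at P0, both lower. With limma 0 genes were called higher, 1576 genes had an unadjusted p under 0.05, and 43 passed at an adjusted p under 0.10, of which 34 were higher and 9 lower in knockouts. Shuffled genotype labels at P0 gave a median of 1177 genes with an unadjusted p under 0.05. Of 100 splits, the true one included, 19 gave as many as the true one. Man1a2 lost its call without any of P0 knockouts 2, 3, 4 and 6 (adjusted p = 0.0933, 0.0909, 0.0993 and 0.0789), P0 wild type 2 (0.102) or P0 wild type 5 (0.0705), at a log2 difference of -1.62 to -1.71. Man1a2 also lost it with array weights (0.0631), the arrays compared alone (0.467), a replicate block (0.186), the running sample number (0.0623) or the marker means as covariates (0.111), and without the marker-rich arrays (0.536). In each of these 6 settings the count was 1, and Man1a2 had a log2 difference of -1.47 to -1.71. The count was 45 without P0 knockout 1, 40 without P0 wild type 1 and 11 without P0 wild type 3. Just short of the threshold, at adjusted p = 0.0952, were Reg2, Pla2g1b, the lipoprotein lipase inhibitor Angptl4 (-0.79 ± 0.14), the carboxypeptidase Cpd (-0.32 ± 0.06) and the amino acid transporter Slc7a8 (-1.33 ± 0.29). Each was below the wild-type mean in 6 of 6 knockouts, and Reg2 below every wild-type array. Angptl4 had a mean signal of 4.9 in knockouts, near the array medians, so the size of its difference is uncertain. On the higher side these were Sap30 (0.74 ± 0.16, adjusted p = 0.0952), Tnfaip8l2 (0.45 ± 0.10), Hoxc4 (0.27 ± 0.06), Tfcp2l1 (0.64 ± 0.15) and Tsc1, a negative regulator of mTORC1 (0.30 ± 0.07, adjusted p = 0.137). Each of these was above the wild-type mean in 6 of 6.

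**Figure D4:**
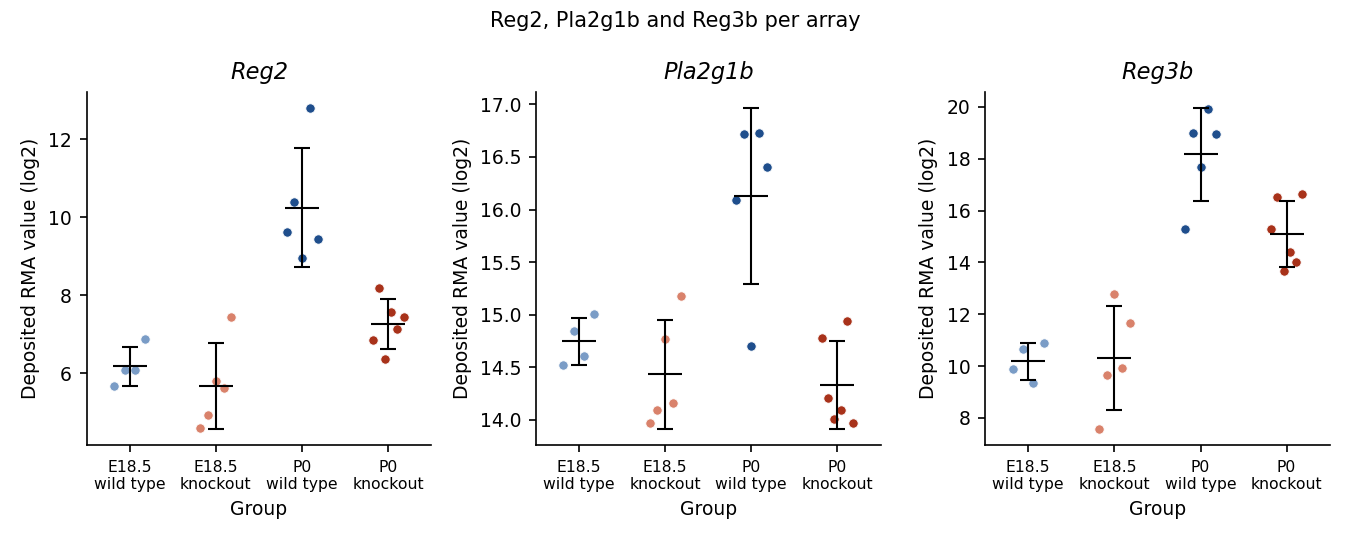
Log2 signal of Reg2, Pla2g1b and Reg3b by genotype and age, with each dot an array, lines the group means and bars the SD. For Reg2, P0 knockouts lie between 6.36 and 8.20 and P0 wild types between 8.97 and 12.8.

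The beta-cell and insulin signalling lists did not pass at P0 either. The beta-cell list had 13 of 21 members above 0 (median 0.085, adjusted p = 0.724), with neuropeptide Npy at 2.78 ± 1.05 and the oxidoreductase Ero1b, which folds proinsulin, at -0.97 ± 0.25. Over all genes 0 of its members were called, and adjusted over the list alone 1 was called lower. Npy was highest on E18.5 knockout 1 (16.02), where Th, a gene of catecholamine synthesis, was also highest (9.11). Among P0 knockouts both were lowest on array 5 (8.67 and 5.08). E18.5 knockout 2 had a higher Npy (10.65) at a similar Th (5.11). Whether nerve or adrenal RNA raised Npy was not tested, so its rise is not read as a beta-cell change. The insulin and IGF signalling list had 19 of 33 members above 0 (median 0.018, adjusted p = 0.316), with Foxo3 at 0.61 ± 0.20, and 1 member called higher adjusted over the list alone. Irs2, an insulin receptor substrate, stood at 1.01 ± 0.48, adjusted p = 0.569 (higher in 5 of 6 knockouts), and Ccnd2, a D cyclin of beta cells, at -0.79 ± 0.32, adjusted p = 0.538 (lower in 5 of 6). Gcg, Sst, Ppy, Pdx1, Nkx6-1, Irs1, Igf1r and Mki67 lay between -0.46 and 0.43, none with an adjusted p under 0.623. Of the genes of neuroendocrine granules and exocytosis, 19 of 24 were above 0 (median 0.11, higher in 6 of 6 knockouts, 0 members called over all genes or over the list alone). This list was called by camera (adjusted p = 0.0288) but not with an estimated correlation (adjusted p = 0.595) or with the marker means as covariates (0.102). Markers of neurons and Schwann cells, which also use this machinery, were above 0 in 13 of 14 cases (median 0.43, higher in 6 of 6 knockouts, adjusted p = 0.00513, and adjusted p = 0.595 with an estimated correlation). The camera call of the neuroendocrine granule list was also lost without any of P0 knockouts 1, 2, 3 and 5 and P0 wild types 1 and 5 (adjusted p from 0.0529 to 0.204). The non-beta islet list was not called at P0 (adjusted p = 0.406).

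Averaged over both ages, Elapor1 (-5.52 ± 0.13, adjusted p = 4.24e-15) and Man1a2 (-1.98 ± 0.19, adjusted p = 4.49e-05) were lower in knockouts. The third gene called was Gm23336, a small nuclear RNA gene annotated inside Elapor1, at -1.30 ± 0.19 (adjusted p = 0.0107). Its signal in knockouts, 3.41 to 4.30, lay below the array medians, so the size of this difference is uncertain. As a predicted gene it fell outside the rule for named genes and was chosen after its values were seen. Mitotic genes were above 0 in 31 of 31 cases (median 0.22, camera adjusted p = 4.08e-12, and adjusted p = 0.551 with an estimated correlation), with Nusap1 at 0.28 ± 0.09. Cholesterol synthesis genes were above 0 in 16 of 18 (median 0.18, adjusted p = 0.000164, and adjusted p = 0.611 with an estimated correlation), among them farnesyl diphosphate synthase Fdps (0.92 ± 0.25). Matrix genes were below 0 in 21 of 22 (median -0.12, adjusted p = 1.32e-06, and adjusted p = 0.551 with an estimated correlation). This average came mainly from E18.5: at P0 alone 12 matrix genes were below 0 and 10 above. Camera also called the difference between ages for this list (adjusted p = 0.00087). The non-beta islet list was above 0 in 7 of 9 (median 0.16, adjusted p = 0.0398, and adjusted p = 0.681 with an estimated correlation), and lost its call without any of 11 single arrays (adjusted p from 0.0504 to 0.197).

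All 3 genes called on average were lower. With limma 0 genes were called higher, and 1180 genes had an unadjusted p under 0.05. Without the marker-rich arrays the count was 2, and without P0 wild type 3 it was 5. A replicate block also gave 3 genes, 1 higher and 2 lower, and kept 2 of the reported calls. Adjusted over the list alone, 1 mitotic gene and 1 cholesterol synthesis gene were called higher and 0 matrix genes were called. For lists the count was 14 of 41, 1 with an estimated correlation, 12 without the marker-rich arrays, 8 without E18.5 knockout 1, 7 without E18.5 wild type 4 and 9 without P0 wild type 1. Cholesterol synthesis was among those lost without the marker-rich arrays (adjusted p = 0.403). Genes with the smallest p-values short of the threshold were Gpx2 (0.28 ± 0.06, adjusted p = 0.357), Ndufaf3 (0.38 ± 0.08), Ppp2r3c (0.21 ± 0.04), Kdm1a (0.25 ± 0.05) and glycogenin Gyg (0.27 ± 0.06) on the higher side. On the lower side were Pla2g1b (-1.05 ± 0.24, adjusted p = 0.42), Angptl4 (-0.43 ± 0.11), Lhfpl2 (-0.21 ± 0.05), Reg2 (-1.75 ± 0.44) and Elfn1 (-0.18 ± 0.05), of which Angptl4 and Elfn1 had signals near the array medians.

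Whether inceptor loss acted differently at the 2 ages was tested as the P0 difference minus the E18.5 difference. Respiratory chain genes shifted down with this contrast, 36 of 38 below 0 (median -0.28, camera adjusted p = 6.96e-10, and adjusted p = 0.609 with an estimated correlation), with Uqcrc2 at -0.49 ± 0.16 and Ndufs3 at -0.33 ± 0.11. Beta oxidation genes were below 0 in 17 of 19 cases (median -0.41, camera adjusted p = 1.65e-06, and adjusted p = 0.242 with an estimated correlation), among them Acadl (-1.03 ± 0.35). S phase genes were below 0 in 24 of 25 cases (median -0.25, camera adjusted p = 0.000368, and adjusted p = 0.763 with an estimated correlation), with Mcm3 at -0.70 ± 0.32. Immediate early and heat shock genes were above 0 in 17 of 17 cases (median 0.38, camera adjusted p = 1.65e-06, and adjusted p = 0.156 with an estimated correlation), with Zfp36 at 1.59 ± 0.53. FOXO targets were above 0 in 13 of 16 cases (median 0.41, camera adjusted p = 0.00087, and adjusted p = 0.609 with an estimated correlation), with Sesn1 at 2.15 ± 1.15. Their adjusted p was 0.162 with the marker means as covariates.

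Gene by gene, limma called 0 genes for this difference between ages, with 1256 genes at an unadjusted p under 0.05 and a smallest adjusted p = 0.261. Without P0 wild type 1 the count was 34, and without the marker-rich arrays it was 0. Camera called 11 of 41 lists, 0 with an estimated correlation, 10 without the marker-rich arrays and 6 with the marker means as covariates. Adjusted over the list alone 0 members of the 5 lists just described were called. The ADP/ATP carrier Slc25a5 (-0.82 ± 0.18), Rida (-0.81 ± 0.18), Cldn10 (-0.62 ± 0.14), Cpd (-0.42 ± 0.09) and Shisal1 (-0.40 ± 0.09) had the smallest p-values below 0. Hoxc4 (0.45 ± 0.09), dystonin Dst (0.52 ± 0.11), Tmod2 (0.54 ± 0.13), Atxn7l1os2 (0.65 ± 0.16) and Vmn1r168 (0.64 ± 0.16) had the smallest above 0, the last 2 at signals near the array medians. Elapor1 itself stood at 0.053 ± 0.26, adjusted p = 0.99. Liver markers were above 0 in 13 of 14 cases (median 2.46, adjusted p = 5.21e-05, adjusted p = 0.613 with an estimated correlation, and adjusted p = 0.0975 without the marker-rich arrays).

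Across genes, the change with inceptor loss at E18.5 and that at P0 had a Pearson r of -0.065 and a Spearman rho of -0.029 over 17993 genes, which are not independent replicates. In 75 of 100 draws of shuffled genotype labels Pearson's r was as high (range of the others -0.307 to 0.228). Of 581 genes with an unadjusted p under 0.01 at either age, 48.9% had the same sign at the other age, against a median of 48.7% in the draws. Genes beside Elapor1 did not stand apart by their median difference, which a change of a few genes would not move. The 50 tested genes on each side in gene order had a median log2 difference of 0.025 at E18.5, 0.0084 at P0 and 0.013 on average. Of random stretches, 45.3%, 65.7% and 57.9% lay as far from 0. Among these neighbours 9, 11 and 9 genes had an unadjusted p under 0.05, as many as in 11.6%, 22.9% and 22.6% of 10000 random stretches. With 100 genes on each side, 17 did so at E18.5, as many as in 4.79% of random stretches. At P0 and on average 16 and 12 did so (63.15% and 62.2%). The stretch of 100 holds Man1a2, while that of 50 does not, as 84 tested genes lie between Man1a2 and Elapor1.

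The comparison of ages in wild type asked how the pancreas differed between E18.5 and P0. Cholesterol synthesis genes fell together, 16 of 18 over all genes and 18 adjusted over the list alone, at a median of -1.28. The largest of these falls were those of the sterol sensor Insig1 (-3.18 ± 0.40), Fdps (-3.13 ± 0.37), Hmgcs1 (-2.65 ± 0.40) and Idi1 (-2.47 ± 0.24). Fatty acid oxidation went the other way, with 8 of 19 members higher (13 adjusted over the list alone), among them the mitochondrial gatekeeper Cpt1a (1.95 ± 0.22), Acadl (1.64 ± 0.26) and Pdk4 (4.63 ± 0.91), which blocks pyruvate entry into the mitochondrial cycle. Glycolysis fell in 5 of 17 genes (9 adjusted over the list alone), including lactate dehydrogenase Ldha (-1.29 ± 0.26) and the glucose transporter Slc2a1 (-1.63 ± 0.27). The hypoxia list fell in 11 of 20 with 1 higher (11 and 1 adjusted over the list alone), led by Egln3 (-2.04 ± 0.35) and Ndrg1 (-1.71 ± 0.28). Endoplasmic reticulum chaperones and unfolded protein response genes fell in 11 of 26 cases with 1 higher (21 and 1 adjusted over the list alone), among them Edem1 (-1.45 ± 0.21) and Sdf2l1 (-1.17 ± 0.27).

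Pancreatic cell type genes changed with age as well. Acinar transcription factors and secretory genes fell in 6 of 16 cases (7 adjusted over the list alone), including Ptf1a (-3.03 ± 0.59), which specifies the acinar lineage, and Bhlha15 (-1.79 ± 0.33). Beta-cell genes fell in 4 of 21 cases (5 lower and 1 higher adjusted over the list alone), including the transcription factor Nkx6-1 (-0.52 ± 0.14, adjusted p = 0.0278) and the proinsulin convertase Pcsk1 (-0.69 ± 0.15). Gcg rose by 0.50 ± 0.15 (adjusted p = 0.0476, higher in 5 of 5 P0 arrays). Its adjusted p lay close to the threshold, and whether the call held with single arrays left out was not examined. Mitotic genes fell in 3 of 31 cases (4 adjusted over the list alone), among them Bub1 (-0.55 ± 0.11) and Ube2c (-0.88 ± 0.16). The largest rises were those of the antimicrobial lectin Reg3b (7.97 ± 0.98), Pdk4, the zymogen granule protein Gp2 (4.10 ± 0.75), Reg2 (4.07 ± 0.65), haem oxygenase Hmox1 (2.79 ± 0.38), Txnip (2.10 ± 0.53), Cpt1a, the fatty acid transporter Cd36 (1.92 ± 0.21), Ifi27l2a (1.90 ± 0.44) and Reg3g (1.88 ± 0.46). The largest falls outside the groups above were those of the mucus disulfide isomerase Agr2 (-4.02 ± 1.09), the chloride transporter Slc26a9 (-3.55 ± 0.47), the glial fatty acid binding protein Fabp7 (-2.06 ± 0.45) and Kctd14 (-2.05 ± 0.42). All 4 were lower in 5 of 5 P0 arrays than in every E18.5 array. Reg3g had a mean signal of 4.69 at E18.5, near the array medians, so the size of its rise is uncertain.

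In wild type 1594 genes were called, 856 higher and 738 lower at P0, of which 225 changed by more than 2-fold. The count was 1499 without the marker-rich arrays, 743, 670 and 943 without E18.5 wild type 1, 2 and 3, 981 without P0 wild type 3, 1008 from the wild-type arrays alone and 552 with a replicate block. Some calls were lost when a single array was left out. Agr2 had adjusted p = 0.0546, 0.0838, 0.0693 and 0.0705 without E18.5 wild type 2 or 4 or P0 wild type 3 or 5, at a log2 difference of -2.88 to -4.34. Txnip had 0.0513, 0.0551 and 0.0503 without E18.5 wild type 1 or 2 or P0 wild type 5, at 1.85 to 2.13. Without E18.5 wild type 2 the values were 0.0546 for Reg3g, 0.0552 for Sdf2l1 and 0.05003 for Ifi27l2a, the latter also 0.0521 without E18.5 wild type 3. Their log2 differences were then 1.86, -0.98 and 1.65 to 1.83. Without the marker-rich arrays the calls of Agr2 and Reg3g were also lost. Camera called 23 of 41 lists, 20 without the marker-rich arrays. Cholesterol synthesis alone kept its call with an estimated correlation (camera adjusted p = 3.79e-25, and adjusted p = 0.0452 with an estimated correlation), and its list mean was lower in 5 of 5 P0 arrays.

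For the other wild-type groups, the camera adjusted p and then the adjusted p with an estimated correlation were those of fatty acid oxidation (1.03e-06 and 0.163, median 0.40), glycolysis (4.17e-07 and 0.2, median -0.48) and hypoxia (8.58e-08 and 0.184, median -0.71). In the same order they were, by list, chaperones (7.79e-10 and 0.176, median -0.59), acinar transcription factors (0.000116 and 0.277, median -0.40), beta-cell genes (0.0149 and 0.41, median -0.28) and mitotic genes (0.00016 and 0.57, median -0.22). For each of these 7 lists the mean lay on the side of the median in 5 of 5 P0 arrays. Liver markers were below 0 in 12 of 14 cases between the ages (median -1.50, adjusted p = 0.0236, and adjusted p = 0.638 with an estimated correlation). Their call was lost without E18.5 wild type 3 (0.093) or 4 (0.111), P0 wild type 1 (0.112) or 5 (0.237). Intestinal markers had a median of -0.72 (adjusted p = 0.408) and skeletal muscle markers one of 0.0049 (adjusted p = 0.925). Mothers of E18.5 litters were starved for 2 h and P0 pups for 5 h, so age and feeding cannot be separated. Running sample numbers lay between 1 and 12 at P0 and between 13 and 22 at E18.5, so age and sample order cannot be separated either.

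**Figure D5:**
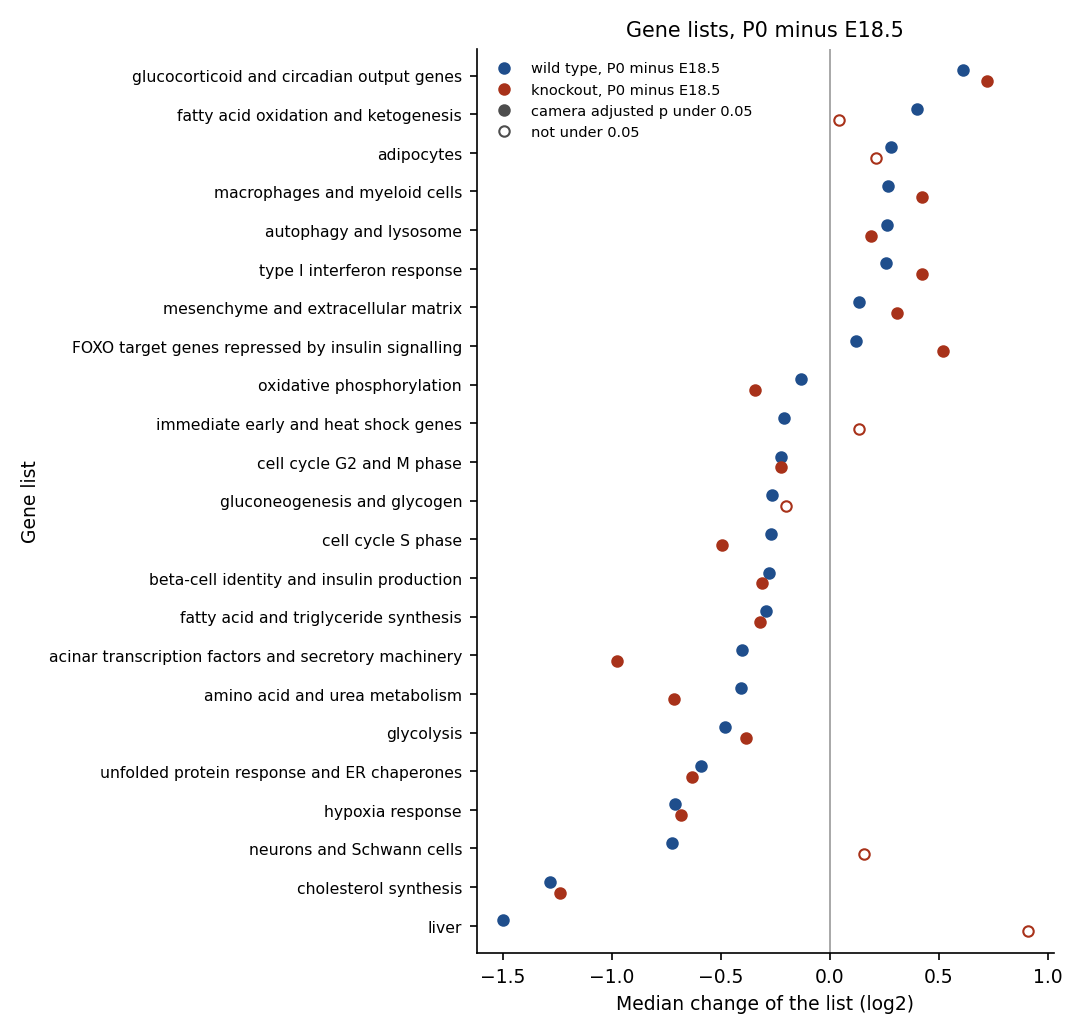
Median log2 difference (P0 minus E18.5) in wild type and in knockouts of the gene lists with a camera adjusted p under 0.05 in either genotype, which filled markers show. Cholesterol synthesis lies at -1.28 in wild type and -1.24 in knockouts, and liver at -1.50 and 0.91.

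The same comparison of ages was made in knockouts. The direction of a list described for 1 genotype was mostly the same in the other. In wild type, FOXO targets were above 0 in 14 of 16 cases and glucocorticoid and circadian output genes in 17 of 19. Respiratory chain genes were below 0 there in 29 of 38 cases and S phase genes in 23 of 25. In knockouts, glycolysis was below 0 in 14 of 17 cases, hypoxia in 16 of 20 and chaperones in 20 of 26. Fatty acid oxidation was above 0 there in 10 of 19 cases, with the list mean higher in 6 of 6 P0 arrays. Cholesterol synthesis fell in 18 of 18 genes (18 adjusted over the list alone; median -1.24), with Hmgcs1 at -2.81 ± 0.36, Fdps at -2.73 ± 0.34, Idi1 at -2.71 ± 0.21 and Insig1 at -2.63 ± 0.36. S phase genes fell in 21 of 25 cases (21 adjusted over the list alone; median -0.49), among them Tyms (-0.98 ± 0.18) and Pcna (-0.81 ± 0.15). Respiratory chain genes fell in 25 of 38 (27 adjusted over the list alone; median -0.34), among them cytochrome c, Cycs (-1.20 ± 0.23). FOXO targets rose in 9 of 16 cases (11 adjusted over the list alone; median 0.52), led by Pdk4 (4.52 ± 0.82) and the stress-responsive Sesn1 (4.26 ± 0.77). Glucocorticoid and circadian output genes rose in 13 of 19 (14 adjusted over the list alone; median 0.72), with Errfi1 at 2.82 ± 0.60 and Fkbp5, a glucocorticoid receptor co-chaperone, at 1.72 ± 0.44. Acinar transcription factors and secretory genes fell in 12 of 16 cases (14 adjusted over the list alone; median -0.98), including Ptf1a (-3.0 ± 0.53) and Rbpjl (-2.61 ± 0.29).

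Beta-cell genes fell in 6 of 21 cases in knockouts (7 adjusted over the list alone; median -0.31), among them Ero1b (-1.59 ± 0.25), with Nkx6-1 at -0.40 ± 0.12, adjusted p = 0.0262, lower in 6 of 6 P0 arrays. Pdx1 was also called (-0.31 ± 0.11, adjusted p = 0.039), but its mean signal of 4.93 at E18.5 and 4.62 at P0 lay near the array medians, so this is not read as a fall of the transcript. The cyclin gene Ccnd2 fell by 1.82 ± 0.32 on the log2 scale (adjusted p = 0.000711). Igf1r rose by 0.38 ± 0.12 (adjusted p = 0.0253). Both did so in 6 of 6 P0 arrays. The largest rises were those of Reg3b (4.76 ± 0.89), Pdk4, Sesn1, Gp2 (4.01 ± 0.67), Ifi27l2a (3.52 ± 0.40), the G protein regulator Rgs2 (3.31 ± 0.61), the glutamine synthetase pseudogene Glns-ps1 (3.10 ± 0.84), Trp53inp1 (3.10 ± 0.55), Hmox1 (3.0 ± 0.34) and Errfi1. The largest falls, besides those named above, were those of Agr2 (-5.92 ± 0.98), the goblet cell gene Spink4 (-4.18 ± 1.20), the BMP antagonist Sostdc1 (-3.41 ± 0.73), Slc26a9 (-3.24 ± 0.43) and Clca1 (-3.13 ± 1.05), another goblet cell product whose mean of 3.95 at P0 lay below the array medians. Clca1 lost its call without E18.5 knockout 1 or 4 (adjusted p = 0.118 and 0.121) or without any single P0 knockout (from 0.0552 to 0.0608), and Spink4 without E18.5 knockout 4 (adjusted p = 0.0561). The log2 differences were then -2.19 to -3.15 and -3.44.

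In knockouts 4139 genes were called between the ages, 2027 higher and 2112 lower at P0, of which 623 changed by more than 2-fold. The count was 1191 without the marker-rich arrays of both genotypes and 2128 with the liver and intestinal marker means as covariates. Without the marker-rich arrays Clca1, Cycs, Errfi1, Fkbp5, Glns-ps1, Ptf1a, Reg3b, Rgs2, Sesn1, Sostdc1, Spink4, Trp53inp1 and Tyms were no longer called. Camera called 17 of 41 lists, 19 without the marker-rich arrays, and none kept the call with an estimated correlation. The pairs of camera adjusted p and adjusted p with an estimated correlation were those of cholesterol synthesis (6.85e-19 and 0.139), S phase (1.19e-09 and 0.279), respiratory chain (6.17e-11 and 0.228) and FOXO targets (3.94e-05 and 0.228). In the same order they were, for the other groups, glucocorticoid and circadian output (1.51e-07 and 0.228), acinar transcription factors (5.18e-08 and 0.228) and beta-cell genes (0.00411 and 0.279). For each of these 7 lists the mean lay on the side of the median in 6 of 6 P0 arrays. Liver markers had a median of 0.91 (adjusted p = 0.269), intestinal markers of -0.94 (0.117) and skeletal muscle markers of 0.091 (0.894). Of the genes called in each genotype, 1209 were shared and all 1209 changed in the same direction. Independent sets would share 183 genes changed in the same direction. Over the 4524 genes called in either, 94.3% had the same sign in both, and across genes the 2 age differences had a Pearson r of 0.725. The difference between the genotypes in these age changes is the same contrast as the difference between ages in the effect of inceptor loss, in which limma called 0 genes, with 1256 at an unadjusted p under 0.05.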

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

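The splits of the arrays were fixed in advance. The tests of the 3 patterns (Man1a2, the Reg2 group and the knockout age count) and the split counts without the targeted locus were chosen after those results were seen, as were the marker covariates, the limit of 7 on the marker means and the arrays over it. Single arrays far from the others of their group, by the gap to the nearest array as a share of the group's range, numbered 29 of 363 group values of named genes and marker means (8%), and chance alone gives about 1 in 20 (5.0%). Values are log2 signals. In the E18.5 knockout group, array 1 was highest for Pdx1 (5.05) and the skeletal muscle marker mean (7.01) and lowest for Ccnd2 (13) and Elapor1 (5.79). Array 2 was highest for the intestinal marker mean (8.43). Array 3 was highest for Nkx6-1 (6.49) and lowest for Kdm1a (9.46). Array 5 was highest for Errfi1 (9.29) and Fkbp5 (6.12). In the E18.5 wild type group, array 1 was lowest for Bub1 (7.02) and Hmox1 (7.28). Array 4 was highest for Agr2 (16.96) and Sesn1 (11.1). In the P0 knockout group, array 1 was highest for Gcg (17.3) and lowest for Gp2 (12.8). Array 2 was highest for Btg2 (10.6). Array 4 was highest for the skeletal muscle marker mean (7.47). Array 5 was highest for Man1a2 (8.39) and lowest for Errfi1 (9.13) and Npy (8.67). Array 6 was highest for the intestinal marker mean (7.08) and lowest for Ins2 (18.5). In the P0 wild type group, array 1 was highest for the skeletal muscle marker mean (5.71). Array 3 was lowest for Hadha (9.43) and Nr5a2 (9.77). Array 4 was lowest for Dst (8.05) and Tnfaip8l2 (5.28). Array 5 was lowest for Mki67 (10.2) and Pcsk1 (6.55).

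Man1a2 was lower in knockouts at both ages, by a mean of -1.98 ± 0.19. RNA of neighbouring organs was argued against as the whole cause, as the difference was -1.91 ± 0.18 (adjusted p = 8.74e-05) with the liver and intestinal marker means as covariates, and -1.90 ± 0.25 (adjusted p = 0.0387) without the 5 marker-rich arrays. A candidate explanation is sequence that travelled with the targeted allele: Man1a2 lies on the same chromosome as Elapor1, and 0.945% of tested genes lie as near to it in gene order, so a gene drawn at random would seldom be so close. The labels name C57BL/6J but not the strain in which the allele was made, and an allele made in C57BL/6J would bring no differing sequence, so this could not be checked further. Of the 84 tested genes between the 2, 6 had an unadjusted p under 0.05 and limma called 0, and an effect of inceptor loss on Man1a2 itself stays open and was not tested.

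Reg2, Pla2g1b and Reg3b were lower in P0 knockouts, at -2.99, -1.79 and -3.08 (adjusted p = 0.0952, 0.0952 and 0.387), while with age they changed by 4.07, 1.38 and 7.97 in wild type and by 1.59, -0.10 and 4.76 in knockouts; the wild-type change of Pla2g1b lost its call without E18.5 wild type 1, 2 or 3 (adjusted p = 0.0691, 0.0552 and 0.0583, at 1.31 to 1.42). A smaller share of acinar RNA would lower acinar genes alike. The median of the 17 other acinar genes below the ceiling was -0.21 and the lowest -1.19, against -2.99 for the pattern. The pattern's genes were picked as low, so part of this gap was fixed in advance and it does not decide against this cause. An equal delay of all age-changed genes was examined over 20 cross-fits. Their signed P0 difference was a median of 0.043 of their age change (-0.14 to 0.24). For the 3 genes, picked as low, it was -0.74, -1.31 and -0.39 in the same cross-fits. The age-changed genes lay above 0.5 times the median of the 3 in 20 of 20. This comparison was also partly fixed in advance, so it does not decide against an equal delay. It shows only that age-changed genes as a set had no delay of the size seen in the 3. A smaller or uneven delay cannot be told apart from a change of the 3 genes alone, because the range of the age-changed genes spans 0. Litter, which the labels do not give, also stays open and untested. The cross-fits replaced a comparison of first component scores (P0 knockout minus wild type 8.27 ± 6.02, exact permutation p = 0.188; E18.5 -9.62 ± 4.67, exact permutation p = 0.111), which had been seen and could not have decided.

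Between the ages 4139 genes were called in knockouts and 1594 in wild type. More knockout arrays do not account for all of this: over 30 choices of 4 E18.5 and 5 P0 knockouts the lowest count was 2781 (median 3151.5, highest 4355). Arrays with RNA of neighbouring organs are a candidate explanation, because the count without the 4 knockout arrays with high intestinal or muscle markers was 1303, as low as in 2 of 100 choices of as many arrays, this one included (the others 1248 to 3625, median 2307). The median size of the age change was 0.16 in wild type and 0.17 in knockouts, with a median SE of 0.13 and 0.12. A stronger response to birth in knockouts stays open, and the test of the difference itself, by limma, called 0 genes with 1256 at an unadjusted p under 0.05.

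Other splits of the arrays tell whether chance can be excluded. For the counts between ages they cannot tell age from feeding or sample order. Chance was excluded for the gene counts between ages in wild type (1594; 1 of 100 splits gave as many; highest other 671) and in knockouts (4139; 1 of 100; 2472), and for the wild-type age lists (23; 1 of 100; 21). For genotype, the true grouping calls Elapor1 by design, so the full counts at E18.5 (2 genes; 4 of 100; highest other 26, in a split that put E18.5 knockouts 1, 2 and 4 with wild type 4) and on average (3; 1 of 100; highest other 1) decide nothing. Without Elapor1 and Gm23336, 1 gene was left in each, Man1a2. Chance was then excluded on average (3 of 100) but not at E18.5 (10 of 100) or P0 (21 of 100). The E18.5 split with 26 and a P0 split with 366 call several times the real counts, which points to a structure among the samples other than genotype. The mean of the FOXO targets was at least 8.77 on the arrays of one side of that P0 split and at most 8.72 on the other. Chance was also not excluded for all genes at P0 (2 genes; 9 of 100; highest other 366, in a split that exchanged P0 knockouts 2, 3 and 6 with wild types 1, 2 and 4) or for the difference between ages (0; 100 of 100; highest other 3; 1256 genes at an unadjusted p under 0.05 with limma). For lists chance was not excluded at E18.5 (11 lists; 41 of 100; highest other 18), P0 (15; 7 of 100; 22), on average (14; 18 of 100; 19), for the difference between ages (11; 41 of 100; 19) or between ages in knockouts (17; 14 of 100; 20).

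A difference between the ages in the response to inceptor loss, by the camera test of the difference itself, picked out 11 lists, with these adjusted p: FOXO targets 0.00087, acinar transcription factors 0.00108, S phase 0.000368, respiratory chain 6.96e-10, fatty acid oxidation 1.65e-06, immediate early genes 1.65e-06, glucocorticoid and circadian output genes 0.00184, interferon response 0.0466, mesenchyme 0.00087, neurons and Schwann cells 0.000368 and liver 5.21e-05. With an estimated correlation 0 lists passed, and their adjusted p ran from 0.156 to 0.943. Without the marker-rich arrays the call ended for acinar transcription factors and glucocorticoid output (adjusted p = 0.0638 and 0.0638), liver (0.0975) and the interferon response (0.828). The interferon call also ended without any of E18.5 knockouts 1, 2 and 4, E18.5 wild types 1 and 4, P0 knockouts 1, 2, 4 and 6 and P0 wild types 1 and 5 (adjusted p from 0.0508 to 0.651).

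Signals also appeared in probe sets that the comparisons do not use. Of 33206 probe sets without a name (16515 tested), 1 was called lower in knockouts at E18.5, 1 at P0 and 1 on average, and 307 and 1223 were called between the ages in wild type and in knockouts. Of 2146 probe sets with several symbols (1307 tested), 115 and 221 were called between the ages in wild type and in knockouts.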

How the results depend on the processing

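Chosen after seeing the data were the marker means as covariates, leaving out the 5 marker-rich arrays, counting duplicate genes once, smaller sets of knockout arrays, and centring and cyclic loess for lists. Elapor1 stayed called in every setting run, at -5.59 to -5.44 at E18.5 and -5.65 to -5.48 at P0, and at -5.61 to -5.42 and -5.61 to -5.38 with 1 array left out. The gene count at E18.5 moved from 2 to 5 with array weights, 1 without the marker-rich arrays and 354 at an unadjusted p under 0.05 with 1.3-fold. At P0 it moved from 2 to 1 with array weights, the arrays compared alone, a replicate block, the running number, the marker covariates or without the marker-rich arrays, to 43 at an adjusted p under 0.10 and to 590 at the unadjusted threshold. The latter gave 150 genes on average (3 as reported; 2 to 3 in the settings that keep the threshold) and 874 for the difference between ages (0 in the others, apart from arrays left out). In wild type the age count of 1594 moved to 1008 with the arrays compared alone, 552 with a replicate block, 2686 and 2482 at the looser thresholds; in knockouts 4139 moved to 2128 with the marker covariates and 1191 without the marker-rich arrays.

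With each array left out in turn, gene counts ran from 2 to 4 at E18.5, 1 to 45 at P0, 3 to 5 on average, 0 to 34 for the difference between ages, 670 to 1822 for age in wild type and 3292 to 4393 in knockouts. List counts ran from 5 to 16, 13 to 17, 7 to 17, 10 to 13, 19 to 23 and 16 to 20 in the same order. With an estimated correlation the list counts were 1, 0, 1, 0, 1 and 0, in the same order, against 11, 15, 14, 11, 23 and 17 as reported. By fry they were 1 at E18.5, 3 at P0, 1 on average, 0 for the difference and 14 for wild-type age, and by fry in either direction 1, 3, 2 and 0 for the first 4 contrasts and 33 for knockout age; with the marker covariates the difference between ages kept 6. The causes were not tested.

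Lists called as reported whose direction reversed, without passing, were cholesterol synthesis at E18.5 (adjusted p = 0.595) and hypoxia on average (0.312) without the marker-rich arrays, and liver at P0 (0.806) with the marker covariates. Single genes that reversed had not passed as reported. At E18.5, Ccnd2 was -0.084 after quantile normalisation, -0.059 with cyclic loess, -0.0064 with the running number and -0.057 with the marker covariates. Irs2 was -0.069 after quantile normalisation, -0.012 after centring, -0.067 with cyclic loess, -0.19 with array weights, -0.080 with the Y-linked level and -0.89 without the marker-rich arrays. Pdx1 was 0.042 and Ppy 0.019 with the running number, Ppy 0.26 with the marker covariates and Sst -0.035 with a replicate block. Ins2 at P0, where its plateau hides any difference, was 0.019 after quantile normalisation and 0.0026 with cyclic loess, which is not read as a change. Leaving out 1 array also reversed Ccnd2 (-0.0065 to 0.15), Irs2 (-0.36 to 0.29), Pdx1 (-0.11 to 0.12), Ppy (-0.23 to 0.20) and Sst (-0.036 to 0.18) at E18.5 and Igf1r at P0 (-0.037 to 0.17). The cause was not tested. Of 2410 values of single genes in the other settings, 2337 kept direction and side of the threshold and 51 fell short of it; of 910 list values, 664 and 243.

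Replicate numbers were not treated as pairs: residual correlations of same-numbered arrays were 0.0904 to 0.229 over 4 pairs at E18.5 and -0.0308 to 0.245 over 5 at P0. The best-matching knockout had the same number for 3 of 4 wild types at E18.5 and 1 of 5 at P0. Structure shared by same-numbered arrays at E18.5 therefore stays open. The age contrasts were not run with the running number, nor the average and the difference with the arrays compared alone. Running numbers did not overlap between the ages. Signal limits the arrays at both ends: 80 tested genes sat at the ceiling on all arrays, and dim genes such as Pdx1 lie near background.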

Other observations

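All values here come from lists fixed in advance. Which of them to describe, and the settings without the marker-rich arrays, were chosen after the results were seen. At E18.5, 3 lists of stromal and immune cells ran lower in knockouts besides the mesenchymal genes, while endothelium (median -0.0057, camera adjusted p = 0.539) and lymphocytes and spleen (median -0.066, camera adjusted p = 0.177) did not pass. Smooth muscle and pericyte genes were below 0 in 15 of 15 cases (list mean lower in 3 of 5 knockouts, median -0.34, camera adjusted p = 0.00591, and adjusted p = 0.669 with an estimated correlation), with desmin Des at -0.60 ± 0.51. Mesothelial genes were below 0 in 9 of 10 (5 of 5 knockouts, median -0.30, camera adjusted p = 0.0058, and adjusted p = 0.669 with an estimated correlation), with Wt1 at -0.50 ± 0.17, and macrophage genes in 15 of 19 (4 of 5 knockouts, median -0.10, camera adjusted p = 0.0058, and adjusted p = 0.601 with an estimated correlation). The smooth muscle call ended without E18.5 knockout 5 or wild type 3 or 4 (adjusted p = 0.144, 0.281 and 0.157), the mesothelial call without wild type 4 (0.092) and the macrophage call without knockout 1 (0.0523) or wild type 4 (0.123). Without the marker-rich arrays these lists had adjusted p = 0.0507, 0.101 and 0.595. Neurons and Schwann cells ran higher in P0 knockouts, 13 of 14 above 0 (list mean higher in 6 of 6 knockouts, median 0.43, camera adjusted p = 0.00513, and adjusted p = 0.595 with an estimated correlation), with Gap43, a growth cone protein, at 0.82 ± 0.47. At E18.5 the same list ran lower, 11 of 14 below 0 (list mean lower in 4 of 5 knockouts, median -0.24, camera adjusted p = 0.0331, and adjusted p = 0.669 with an estimated correlation). That call ended without any of E18.5 knockouts 2, 3, 4 and 5 and E18.5 wild types 1, 2 and 4 (adjusted p from 0.092 to 0.246). No member of these lists was called over all genes, and 0 were called adjusted over the list alone.

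Other metabolic groups changed with age in wild type. Serine, one-carbon and urea genes fell in 5 of 11 cases (5 adjusted over the list alone; median -0.41, camera adjusted p = 0.000856, and adjusted p = 0.187 with an estimated correlation), among them mitochondrial Shmt2 (-1.15 ± 0.13) and Mthfd2 (-0.75 ± 0.16). Fatty acid and triglyceride synthesis fell in 6 of 17 (6 lower and 1 higher adjusted over the list alone; median -0.29, camera adjusted p = 0.00238, and adjusted p = 0.246 with an estimated correlation), including fatty acid synthase Fasn (-1.13 ± 0.14) and the desaturase Fads2 (-1.30 ± 0.27). Autophagy and lysosome genes rose in 6 of 25 with 1 lower (11 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 0.000424, and adjusted p = 0.12 with an estimated correlation), such as the lysosomal membrane protein Lamp2 (0.57 ± 0.09) and Ctsa (0.57 ± 0.13). In knockouts, interferon response genes rose in 5 of 21 cases (11 adjusted over the list alone; median 0.42, camera adjusted p = 0.00014, and adjusted p = 0.486 with an estimated correlation), among them the RNA sensor Ifih1 (0.86 ± 0.21) and Zbp1 (0.43 ± 0.13; adjusted p = 0.0654 at 0.36 without E18.5 knockout 2), neither called without the marker-rich arrays, and mesenchymal genes in 10 of 22 (12 adjusted over the list alone; median 0.31, camera adjusted p = 1.44e-05, and adjusted p = 0.279 with an estimated correlation), such as Fn1 (1.45 ± 0.19) and Postn (1.10 ± 0.16). The list means lay on the side of the median in 5 of 5 wild-type P0 arrays for the amino acid list, 5 of 5 for lipid synthesis and 5 of 5 for lysosomes, and in 6 of 6 knockout P0 arrays for interferon and 6 of 6 for mesenchyme. In wild type, interferon and mesenchymal genes also rose with age, above 0 in 17 of 21 and 18 of 22 cases, and camera called both lists. The interferon call ended without E18.5 wild type 2 or 3 or P0 wild type 2 (camera adjusted p = 0.0693, 0.0607 and 0.441). The mesenchyme call ended without E18.5 wild type 4 (0.0725). In knockouts the amino acid, lipid synthesis and lysosome means moved as in wild type, in 5, 6 and 6 of 6 P0 arrays.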
